A study of Mus musculus with 24 samples.

How the data were processed

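The series holds 24 samples, of which 12 are T cell sufficient lymphomas, 11 T cell deficient lymphomas and 1 a second library of T cell sufficient lymphoma 1 sequenced in run 2 as a link between runs. Per the labels' protocols, RNA was isolated from purified B lymphoma cells of the spleen with a column kit and made into TruSeq RNA libraries. Each animal gave 1 lymphoma sample. The authors deposited a table of 11140 genes by symbol with raw counts for 23 libraries, and beside them CPM, counts scaled to the library total. The deposited CPM equal the count over the column total, scaled to CPM, within 5e-04. The repeat library was not analysed here as a library of its own, and the table does not say whether the deepest column, of T cell sufficient lymphoma 1, holds its run 1 library alone or both of its libraries. The column taken for T cell sufficient lymphoma 4 carries that sample's number with another suffix than its label and was matched by the number. The authors also deposited log2 fold changes of T cell deficient over sufficient lymphomas, mean log2 expression, p-values and adjusted p-values. Per the submitters' processing notes, the builds mm10 and GRCm38 and the package limma were used. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here.

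Each listed gene has more than 1 CPM in at least 7 of the 23 deposited libraries, so genes expressed in fewer libraries were not analysed here. No gene symbol in the table holds a hyphen, so the classical MHC genes and the mitochondrially encoded genes were not analysed here, nor were immunoglobulin and T cell receptor segments. The planned shares of the dominant heavy and light chain V genes and the planned comparison with the repeat library were therefore not run. For 19 genes the identifier and the name column differ, and none of them is named. Without a stated counting tool, reads of overlapping genes and of near-identical copies cannot be assigned with certainty. Coordinates are from GENCODE M21 on GRCm38, which holds 10664 of the 11140 symbols.

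Counts were tested as deposited with edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr, which removed 120 and left 11020, library sizes were scaled by TMM, and the quasi-likelihood test with robust dispersion was fitted with terms for run and group. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. The standard error of a log2 fold change is its size over the square root of the F statistic. CPM in the text are scaled by TMM. Log2 CPM for lists, principal components and distances use a prior count of 2. Groups were also compared within each run, with an interaction of group and run, and runs were compared with group as a term. Permutation tests drew 100000 relabellings within runs, and tests within 1 run enumerated every split.

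Before the data were examined, 37 gene lists with 692 genes were fixed, of which 538 have a row, 7 of them through an older symbol. The 32 lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation, and with fry, and adjusted over the 32 lists. Lists share genes, so their tests are not independent. The rule for named genes was also fixed beforehand. It took Cd3e, Bcl6, Tnfsf9 and Tnfrsf9, the 10 largest log2 fold changes in each direction among called genes with a mean log2 CPM of at least 1 and the same sign in both runs, and up to 4 members of each list with the smallest p. Some genes that this rule takes are not reported here.

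The code was tested on simulated counts drawn from the real means, library sizes and dispersions with 200 changed genes. For the comparison over both runs, with 10969 simulated genes tested, 49.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 84.8% of those changed 4-fold were called in the right direction, with 3 calls among unchanged genes. For run 1 alone, with 10958 genes, the shares were 7.46%, 55.2% and 78.8%. For run 2 alone, with 10973 genes, they were 7.46%, 43.3% and 78.8%.

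Total counts ran from 7.58 to 30.6 M per library (M, mega), and 3 counts are worth 0.0980 to 0.396 CPM, which covers counting error only. No 2 libraries held identical counts. Over the 121 pairs within groups, the chi-square of the counts per degree of freedom was at least 31.1, so no pair differed by as little as sampling noise. Alternatives were other scalings, filters, tools (DESeq2 1.42.0, limma-voom), thresholds, covariates, single runs, libraries left out and the replicate number as a block.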

Results

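RNA was sequenced from B lymphoma cells purified from the spleens of C57BL/6 mice that carry a Bcl6 transgene, a model in which B cells go on to form lymphomas. The T cell sufficient group held 12 lymphomas from mice with this transgene alone. The T cell deficient group held 11 lymphomas from transgenic mice labelled as also lacking Cd3e, a subunit of the T cell receptor complex without which T cells do not develop. Libraries were sequenced in 2 runs. Run 1 held 7 T cell sufficient and 5 T cell deficient libraries, and run 2 held 5 and 6. Total counts over the listed genes averaged 15.7 M ± 6.00 (SD, n = 12; M, mega) in the sufficient group, from 7.58 to 30.6 M. They averaged 20.6 M ± 6.03 (SD, n = 11) in the deficient group, from 11.8 to 28.1 M. The deficient libraries were the deeper ones (permutation test within runs, two-sided, p = 0.0438). Lower-expressed genes are thus measured less precisely in the sufficient group. The question the series addresses is how lymphomas that arose without T cells, and so without T cell surveillance, differ from those that arose with them.

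Cd3e, the deleted gene, lay on chromosome 9 at 44998740 to 45009627 (GRCm38, minus strand). It averaged 0.966 CPM ± 0.754 (SD, n = 12) in the sufficient group and 2.47 CPM ± 1.73 (SD, n = 11) in the deficient group. The difference did not pass the test (log2 fold change 1.07 ± 0.57 SE, edgeR adjusted p = 0.179). It was counted in all 11 deficient libraries (0.721 to 5.77 CPM), 4 of them above every sufficient library. The part of the gene that was deleted is not given in the sources used here, so this transcript does not check the genotype labels, and the groups are named as labelled. Bcl6, the transgene's product and a repressor that keeps B cells in the germinal centre programme, lay on chromosome 16 at 23965052 to 23988852. It averaged 591 CPM ± 426 (SD, n = 12) in sufficient and 642 CPM ± 193 (SD, n = 11) in deficient lymphomas, a difference that did not pass the test (log2 fold change 0.07 ± 0.27 SE, edgeR adjusted p = 0.864). These counts do not separate the transgene from the mouse's own Bcl6 gene, so transgene expression by itself was not compared.

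Tnfsf9, which encodes the CD137 ligand named in the study's title, a costimulatory molecule that engages CD137 on activated T cells, was 4.09-fold higher in T cell deficient lymphomas. Its level averaged 113 CPM ± 27.4 (SD, n = 11) there against 32.5 CPM ± 40.8 (SD, n = 12) in T cell sufficient lymphomas (log2 fold change 2.03 ± 0.42 SE). The gene lies on chromosome 17 at 57105325 to 57107757 on the plus strand. The difference passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00212) and a permutation of the groups within runs (two-sided, p = 3e-05). Of the 12 sufficient libraries, 11 were below every deficient library, whose lowest value was 83.5 CPM, and the highest of these 11 was 37.0 CPM. T cell sufficient library 5 stood apart at 158 CPM, above the highest deficient library (157 CPM). Within run 1 the means were 43.3 CPM ± 51.5 (SD, n = 7) and 118 CPM ± 21.005 (SD, n = 5), an exact permutation p of 0.0126 over 792 splits. Within run 2 they were 17.3 CPM ± 10.7 (SD, n = 5) and 110 CPM ± 33.3 (SD, n = 6), an exact permutation p of 0.00216 over 462 splits. With run 1 fitted alone across all genes, the adjusted p of edgeR was 0.253, and without library 5 the log2 fold change over both runs was 2.47 (adjusted p = 1.52e-05). The transcript of Tnfrsf9, the receptor for this ligand, was not analysed here.

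**Figure D1:**
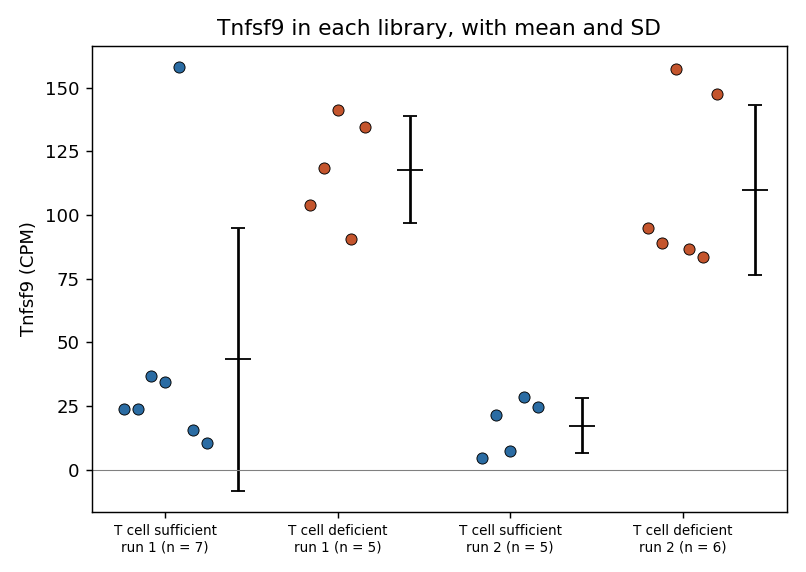
Tnfsf9 in CPM, counts scaled to library size (vertical axis), in each of the 23 libraries, by group and run; points are libraries, and the bars beside them give the mean and SD. The deficient libraries sit at 83.5 CPM or higher, and the sufficient libraries at 37.0 CPM or lower apart from library 5 at 158 CPM.

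Across the 11020 genes tested, 2448 differed between the groups (edgeR's quasi-likelihood test with a term for run, adjusted p under 0.05), of which 1163 were higher and 1285 lower in T cell deficient lymphomas. The changes included 271 higher and 492 lower genes of more than 2-fold, and 116 and 199 of more than 4-fold. Among higher genes, Il1r1, a receptor for interleukin 1, averaged 25.2 CPM ± 17.9 (SD, n = 11) against 0.839 CPM ± 0.978 (SD, n = 12), and all 11 deficient libraries exceeded every sufficient one (log2 fold change 4.81 ± 0.69 SE, adjusted p = 0.00019). Trpm6, a magnesium channel, rose by a log2 fold change of 5.36 ± 0.92 (adjusted p = 0.000689). Stc2, a secreted glycoprotein, rose by 5.56 ± 1.05 (adjusted p = 0.00125), and Csrp2, a LIM domain protein, by 4.01 ± 0.79 (adjusted p = 0.00164). The other members of the 10 with the largest rises were Susd4, Aif1l, Rab44, Cox4i2, Thsd4 and Pcdhgc3, with log2 fold changes from 4.11 to 4.81. The size of the Rab44 rise depended on T cell deficient library 6 (131 CPM), without which its log2 fold change was 2.84 (adjusted p = 0.0106). Rab44 did not pass without the 3 libraries that hold both Xist and Y-linked transcripts (adjusted p = 0.0854). Without deficient library 9, the log2 fold change of Stc2 was 3.93, and Aif1l did not pass with the replicate number as a block (adjusted p = 0.0519). All of these 10 but Il1r1, Pcdhgc3 and Csrp2 averaged from 0.206 to 0.324 CPM in the sufficient group, close to what 3 counts are worth in these libraries (0.0980 to 0.396 CPM), so the size of their folds is loosely fixed. Several were also uneven in the deficient group. There the SD of the CPM exceeded the mean for Stc2, Trpm6, Susd4, Aif1l and Rab44, and lay below it for the others of these 10.

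The largest falls were in genes that the sufficient lymphomas expressed unevenly. Il9r, the interleukin 9 receptor, averaged 29.7 CPM ± 36.1 (SD, n = 12) against 0.469 CPM ± 0.901 (SD, n = 11), a log2 fold change of -5.95 ± 1.01 SE (adjusted p = 0.000684). Serpinb6b, a serine protease inhibitor, averaged 95.9 CPM ± 121 (SD, n = 12) against 2.38 CPM ± 1.61 (SD, n = 11), and 8 of 11 deficient libraries lay below every sufficient one (log2 fold change -5.36 ± 0.79 SE, adjusted p = 0.000217). Tbx21, which encodes the transcription factor T-bet, fell by 5.17 ± 1.18 on the log2 scale (adjusted p = 0.0044). Cyp11a1, the enzyme that starts steroid hormone synthesis, fell by 5.80 ± 1.00 (adjusted p = 0.000734), and Hsd11b1, which activates glucocorticoids, fell by 5.10 ± 0.96 (adjusted p = 0.00122). Col1a1, a collagen chain, was low in both groups (7.49 CPM ± 7.48, SD, n = 12, against 0.223 CPM ± 0.196, SD, n = 11; adjusted p = 0.000151). Parm1, Fras1, Ccr1 and Rcn3 complete the 10 largest falls, with log2 fold changes from -5.30 to -4.99. Without T cell sufficient library 7, the log2 fold change was -4.63 for Cyp11a1 and -3.94 for Ccr1. Without T cell deficient library 7 that of Parm1 was -7.49. With limma-voom, Cyp11a1, Fras1, Hsd11b1, Parm1, Rcn3, Serpinb6b, Stc2 and Tbx21 did not pass the adjusted threshold, and DESeq2 gave no adjusted p for Rab44. In run 2 alone Fras1 did not pass (adjusted p = 0.0603), and Parm1 and Aif1l were not tested there. In run 1 alone Il9r and Susd4 were not tested. Of the 23 fits with 1 library left out, Col1a1 was tested in 12, Parm1 in 13 and Il9r in 14.

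**Figure D2:**
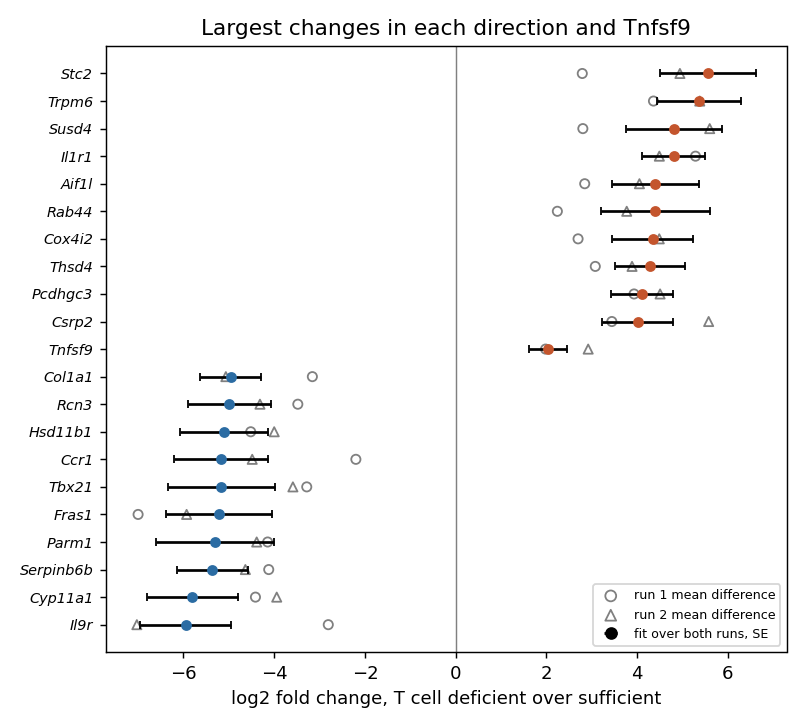
Log2 fold change of T cell deficient over sufficient lymphomas (horizontal axis) for the 10 largest rises, the 10 largest falls and Tnfsf9; filled points and bars give the edgeR estimate over both runs with its SE, open circles and triangles the difference of mean log2 CPM in run 1 and run 2. The estimates over both runs go from -5.95 for Il9r to 5.56 for Stc2. The same sign in both runs was a condition for all genes but Tnfsf9, and the open symbols use a prior count of 2, which draws low genes toward 0.

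Genes of cell division rose together in T cell deficient lymphomas. Of 36 measured members of the proliferation list, 28 rose, 0 fell and 8 did not pass the test (31 rose when adjusted over the list alone). Mki67, a nuclear protein of dividing cells, averaged 1625 CPM ± 775 (SD, n = 11) against 701 CPM ± 365 (SD, n = 12), a log2 fold change of 1.03 ± 0.18 SE (adjusted p = 0.000692). Bub1b, a mitotic checkpoint kinase, rose 1.94-fold and was higher in all 11 deficient libraries than in any sufficient one. Cdc20, an activator of the anaphase-promoting complex, rose 1.84-fold and Ccnb2, a mitotic cyclin, 1.63-fold. The list passed camera with its preset correlation (adjusted p = 5.11e-13; adjusted p = 0.218 with an estimated correlation) and fry (adjusted p = 0.00118). Its median difference was 0.42 in run 1 and 0.64 in run 2 on the log2 scale.

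Germinal centre genes were also higher. Of 23 measured members, 11 rose, 0 fell and 12 did not pass (13 rose when adjusted over the list alone). Gna13, a G protein that confines B cells to germinal centres and is often lost in human lymphoma, averaged 525 CPM ± 151 (SD, n = 11) against 279 CPM ± 66.4 (SD, n = 12), a log2 fold change of 0.93 ± 0.16 SE (adjusted p = 0.000681). Mef2b, a transcription factor of germinal centre B cells, rose 2.25-fold and Il21r, the receptor for the T helper cytokine interleukin 21, 1.84-fold. The list's camera test gave an adjusted p of 6.86e-05 (adjusted p = 0.148 with an estimated correlation), with medians of 0.61 in run 1 and 1.30 in run 2. In the list of MYC targets and ribosome biogenesis, 5 of 30 measured members rose, 0 fell and 25 did not pass (5 rose when adjusted over the list alone). Its median log2 fold change was 0.16, with Gnl3 at 0.43 ± 0.13 and Nop58, a nucleolar protein, at 0.41 ± 0.13. Its camera adjusted p was 0.0133 (adjusted p = 0.813 with an estimated correlation), and it did not pass in run 2 alone (adjusted p = 0.279) or without T cell deficient library 7 (adjusted p = 0.0793), nor by fry (adjusted p = 0.238) or without the run term (adjusted p = 0.071).

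Genes of resting, recirculating B cells were lower in T cell deficient lymphomas. Of 14 measured members of the follicular and naive B cell list, 7 fell, 0 rose and 7 did not pass (9 fell when adjusted over the list alone). Bank1, a B cell scaffold protein, averaged 339 CPM ± 302 (SD, n = 12) against 47.4 CPM ± 24.8 (SD, n = 11), and 7 of 11 deficient libraries lay below every sufficient one (log2 fold change -2.84 ± 0.53 SE, adjusted p = 0.00117). Cd55, an inhibitor of complement, was 5.74-fold lower. This list passed camera (adjusted p = 1.19e-05; adjusted p = 0.0908 with an estimated correlation), with medians of -0.93 in run 1 and -2.03 in run 2.

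Markers of other mature B cell states were lower as well. In the age-associated and memory B cell list, 7 of 13 measured members fell, 0 rose and 6 did not pass (8 fell when adjusted over the list alone). Cd38, a surface enzyme that mouse germinal centre B cells carry at low levels, averaged 403 CPM ± 153 (SD, n = 12) against 42.6 CPM ± 41.9 (SD, n = 11). Its log2 fold change was -3.24 ± 0.45 SE (adjusted p = 0.000163), and all 11 deficient libraries lay below every sufficient one. Fcrl5, an Fc receptor-like protein, was 4.57-fold lower. The memory list had a camera adjusted p of 8.97e-05 (adjusted p = 0.181 with an estimated correlation). In the marginal zone and B-1 cell list, 8 of 18 measured members fell, 0 rose and 10 did not pass (8 fell when adjusted over the list alone). Bhlhe41, a transcription factor of B-1 cells, was 7.56-fold lower, Myof, a membrane repair protein, 6.87-fold lower and Tbc1d9 6.08-fold lower. For this list camera gave an adjusted p of 0.000178 (adjusted p = 0.148 with an estimated correlation). Of the genes in the memory list, 8 of 13 also stood in another list, among them Fcrl5 and Bhlhe41, so these counts are not independent. The monocyte and macrophage list had a median log2 fold change of -0.94 beside these groups (camera adjusted p = 0.0672; adjusted p = 0.813 with an estimated correlation), and it passed in run 2 (adjusted p = 0.00704) but not in run 1 (adjusted p = 0.976).

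Antigen presentation genes fell. All 6 measured members of the MHC class II presentation list had negative changes, of which 5 passed the test and 1 did not (5 fell when adjusted over the list alone). Cd74, the invariant chain that escorts MHC class II, averaged 9683 CPM ± 1650 (SD, n = 12) against 5905 CPM ± 1518 (SD, n = 11), a log2 fold change of -0.70 ± 0.13 SE (adjusted p = 0.00095). Ctss, the protease that trims the invariant chain, was 1.73-fold lower, Ifi30, a lysosomal thiol reductase, 2.49-fold lower and March1, a ubiquitin ligase that removes MHC class II from the surface, 3.81-fold lower. By camera the adjusted p was 8.97e-05 (adjusted p = 0.0908 with an estimated correlation), with medians of -0.82 in run 1 and -0.80 in run 2. In the MHC class I list, 4 of 14 members fell, 0 rose and 10 did not pass (4 fell when adjusted over the list alone). B2m, the light chain of MHC class I, was 1.71-fold lower (log2 fold change -0.77 ± 0.13 SE, adjusted p = 0.000475), Tap2, a subunit of the peptide transporter, 1.34-fold lower. The MHC class I list had a camera adjusted p of 0.0308 (adjusted p = 0.218 with an estimated correlation) and did not pass in run 1 alone (adjusted p = 0.0647), without deficient library 11 (adjusted p = 0.0543) or with Xist and Y-linked covariates (adjusted p = 0.0575). The classical MHC genes themselves were not analysed here.

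Genes of the interferon gamma response and members of the costimulatory and inhibitory ligand list were lower too. Of 27 measured members of the interferon gamma list, 11 fell, 0 rose and 16 did not pass (13 fell when adjusted over the list alone). Cd274, which encodes the inhibitory ligand PD-L1, averaged 71.2 CPM ± 45.9 (SD, n = 12) against 23.8 CPM ± 12.8 (SD, n = 11), a log2 fold change of -1.60 ± 0.30 SE (adjusted p = 0.00114). Cxcl9, a chemokine that attracts T cells, was 7.63-fold lower from 3.64 CPM, and Tap1, the partner of Tap2, 1.32-fold lower. Camera gave an adjusted p that was 8.97e-05 (adjusted p = 0.23 with an estimated correlation), and the list did not pass in run 1 alone (adjusted p = 0.0648, median -0.31, against -0.89 in run 2). Of 27 costimulatory and inhibitory ligands, 11 fell, 0 rose and 16 did not pass (12 fell when adjusted over the list alone). Pdcd1lg2, the PD-L2 gene, was 16.0-fold lower (log2 fold change -4.00 ± 0.69 SE, adjusted p = 0.000697), Slamf1 6.66-fold lower and Ceacam1 2.80-fold lower. These ligands had a camera adjusted p of 0.000776 (adjusted p = 0.0908 with an estimated correlation). Their list does not hold Tnfsf9, Cd70 and Tnfsf14, ligands of the TNF superfamily that rose. Of the macrophage markers, Lyz2, a lysozyme of myeloid cells, was lower too and averaged 153 CPM ± 168 (SD, n = 12) against 38.5 CPM ± 32.9 (SD, n = 11; adjusted p = 0.021), and the median change of the 19 monocyte and macrophage genes was 0.28 in run 1 and -1.26 in run 2.

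**Figure D3:**
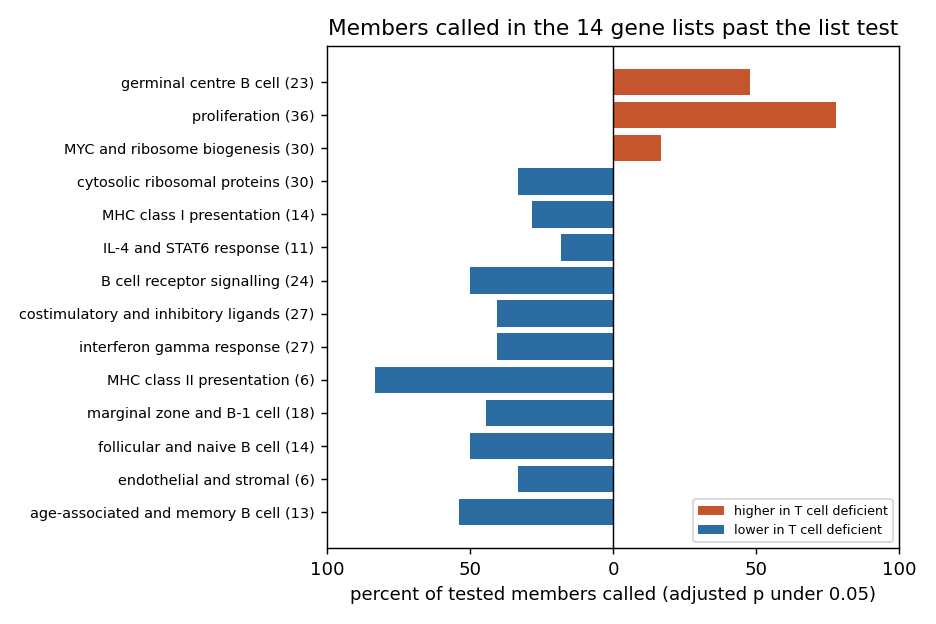
Percent of the measured members of each gene list (horizontal axis) that were called higher (right) or lower (left) in T cell deficient lymphomas at an adjusted p under 0.05; the number of measured members stands in parentheses, and the 14 lists are those past the camera test. Proliferation has 28 of 36 members higher and MHC class II presentation 5 of 6 lower.

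The remaining lists past the camera test were also lower. Of 24 B cell receptor signalling genes, 12 fell, 0 rose and 12 did not pass (12 fell when adjusted over the list alone). Syk, the kinase that transmits the receptor's signal, averaged 1376 CPM ± 469 (SD, n = 12) against 732 CPM ± 235 (SD, n = 11), a log2 fold change of -0.94 ± 0.19 SE (adjusted p = 0.00175). Fcgr2b, an inhibitory Fc receptor, was 2.28-fold lower and Prkcb, a protein kinase C, 1.56-fold lower. Signalling genes had a camera adjusted p of 0.000466 (adjusted p = 0.218 with an estimated correlation). Of 30 cytosolic ribosomal protein genes, 10 fell, 0 rose and 20 did not pass (11 fell when adjusted over the list alone). The median change was -0.16, with Rps14 at -0.56 ± 0.11. Their camera adjusted p was 0.000178 (adjusted p = 0.542 with an estimated correlation), and 0.0625 in run 1 alone. These genes have many near-identical pseudogene copies, so their counts are uncertain. Of 11 genes of the IL-4 and STAT6 response, 2 fell, 0 rose and 9 did not pass (3 fell when adjusted over the list alone). They were Pdcd1lg2 and Hvcn1, a proton channel of B cells (log2 fold change -1.79 ± 0.37). The camera adjusted p was 0.0371 (adjusted p = 0.148 with an estimated correlation), 0.0558 in run 1, 0.0565 in run 2, 0.0816 without deficient library 7 and 0.0503 without the 3 libraries that hold both Xist and Y-linked transcripts. In T cell sufficient library 5 the mean log2 CPM of these genes was 4.22, with the nearest sufficient library of run 1 at 5.23. Of 6 endothelial and stromal genes, 2 fell, 0 rose and 4 did not pass (3 fell when adjusted over the list alone). These were Col1a1 and Kdr, a receptor for vascular growth factor at 2.95 CPM in the sufficient group. The camera adjusted p was 0.0272 (adjusted p = 0.218 with an estimated correlation), and 0.151 in run 1. This list did not pass with a macrophage covariate (adjusted p = 0.0646), with Xist and Y-linked covariates (adjusted p = 0.0808) or without the 3 libraries that hold both (adjusted p = 0.413). With any of 11 sufficient libraries left out, library 5 excepted, Col1a1 fell under the filter on low counts and the list did not pass (adjusted p from 0.105 to 0.246).

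Over the 32 lists with enough measured genes, 14 passed camera with its preset correlation, 3 higher and 11 lower, and 0 passed with an estimated correlation, where 7 had an unadjusted p under 0.05. By fry, which tests whether a list's genes move one way on balance, 15 passed. A permutation of the groups within runs on each list's mean, a test added after the data were examined, gave 14 lists with an adjusted p under 0.05. Of these, 13 were shared with camera; the MYC list did not pass it (adjusted p = 0.187) and the TGF-beta list did (adjusted p = 0.00898). Members of a list vary together between animals, and in splits of the libraries drawn at random within runs camera with the preset correlation passed a median of 7 lists.

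**Figure D4:**
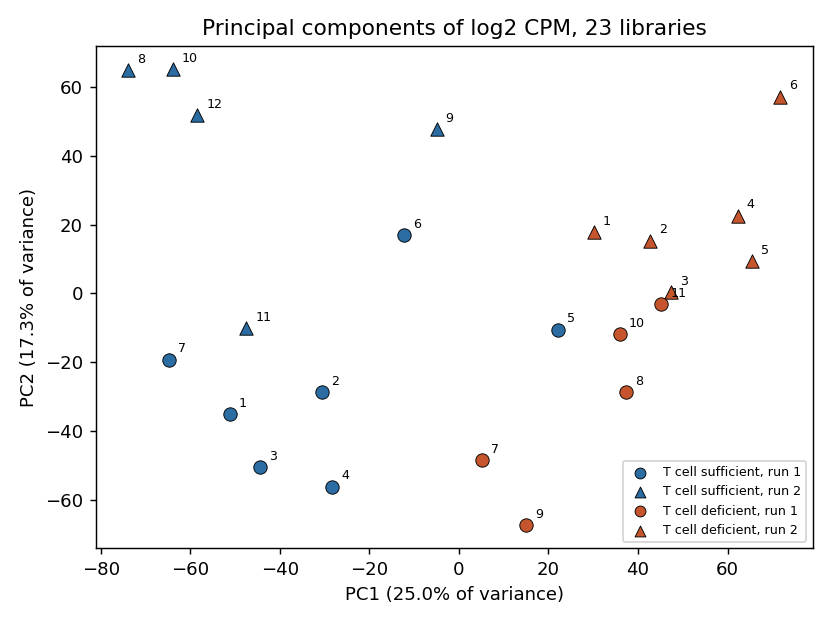
First and second principal components of log2 CPM over the 11020 tested genes; each point is a library with its replicate number, colours give the group and circles and triangles run 1 and run 2. The first component (24.99% of variance) places the deficient libraries at 5.04 or higher and the sufficient libraries below 0 apart from library 5 at 22.2.

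Groups were also compared within each sequencing run. In run 1 (7 sufficient and 5 deficient), edgeR called 0 of 11064 genes, with 1832 at an unadjusted p under 0.05, and 0 were called by limma-voom. In run 2 (5 and 6), edgeR called 1359 of 11051, of which 629 were higher and 730 lower. Of 1339 run 2 calls tested in run 1, 1257 (93.9%) had a difference of the same sign there, against 72.8% of all 10987 genes tested in both runs (Pearson r = 0.636 across genes, which are not independent replicates). When adjusted over the list alone, 291 of these passed in run 1 in the same direction and 1 in the opposite direction. Over the run 2 calls, the median ratio of the run 1 to the run 2 log2 fold change was 0.50. Genes chosen by their run 2 result tend to show larger folds in that run, so this ratio does not measure a smaller effect in run 1. The test for a group difference that depends on run called 0 of 11020 genes in edgeR, with 723 at an unadjusted p under 0.05, so no gene was shown to differ between runs in its group effect. The run 1 count was 191 without T cell sufficient library 5, 2 without sufficient library 6 and 1 without deficient library 8 or 11. The run 2 count fell to 528, 751 and 779 without sufficient libraries 8, 10 and 12, and to 795, 613 and 785 without deficient libraries 2, 4 and 5. The runs themselves differed in 3999 genes, 2048 higher and 1951 lower in run 2. Run was a term in the main fit over both runs, and without it 1753 genes were called.

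The authors' deposited table of the same comparison listed 2535 genes with an adjusted p under 0.05, of which 1228 were higher and 1307 lower in T cell deficient lymphomas. Of these, 2170 were also called here, and all 2170 had the same direction. Across the 11020 genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of 0.943. The authors' deposited table gave Tnfsf9 a log2 fold change of 2.29 and an adjusted p of 0.000404. Among the largest rises and falls named above, Trpm6, Stc2, Aif1l, Rab44, Cyp11a1, Parm1, Fras1, Tbx21, Hsd11b1 and Rcn3 did not pass there. Their deposited adjusted p went from 0.056 for Trpm6 to 0.228 for Parm1, and the others were under 0.05.

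Lymphomas of the deficient group were compared with one another to ask whether they were more alike than those of the sufficient group. The mean distance between animals (1 minus Spearman's correlation over the 1000 most variable genes, run means removed) was 0.754 in the deficient and 0.855 in the sufficient group, a difference of -0.10 (permutation test within runs, two-sided, p = 3e-05). The difference did not hold with the Euclidean distance (-0.23, permutation p = 0.257) or over pairs of the same run with run means kept (0.0032, permutation p = 0.949). Simulated counts with equal spread in both groups and the fitted group effects gave differences from -0.055 to -0.032 (mean -0.042) by the first measure. The simulated genes varied independently of one another, while real genes vary together between animals. The simulated ranges are therefore no measure of how large a difference to look for in the libraries. Without T cell sufficient library 5 the -0.10 of the libraries became -0.046, and no simulation was made for the libraries without it. Over pairs of the same run the simulated counts gave -0.13 to -0.070 (mean -0.10), where the libraries gave 0.0032. The permutation p therefore does not test spread alone.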

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

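The test of depth in run 1 and the range of the ratio of variation with a library left out were chosen after their values were seen, and the alternatives with covariates, thinned counts, libraries left out within a run or several libraries left out were added after the data were examined. Groups of more than 10 libraries were not searched for single extreme libraries; the run and group subsets of 5 to 7 libraries were, 72 in all over totals, Tnfsf9, Bcl6, Cd3e and the 14 lists past the camera test, and 8 had a library far from the others. Chance gives about 1 in 20. In run 1, T cell sufficient library 5 had 158 CPM of Tnfsf9 against 37.0 in the nearest library, and a mean log2 CPM of IL-4 and STAT6 response genes of 4.22 against 5.23. Bcl6 was 1056 CPM in sufficient library 4 (nearest 482) and 1799 CPM in sufficient library 11 (nearest 514). The mean log2 CPM of MHC class I genes was 8.56 in sufficient library 6, with the nearest at 8.62. That of MHC class II genes was 8.83 in sufficient library 9 of run 2, with the nearest at 9.18. In run 1, that of age-associated and memory B cell genes was 5.004 in deficient library 7 (nearest 3.58) and that of follicular and naive genes 4.74 in deficient library 9 (nearest 5.47).

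Xist, made from the inactive X chromosome, and Y-linked transcripts stood together in 3 sufficient libraries of run 2, a signal in genes that no comparison above reports. Ddx3y was 22.2 CPM in library 9 (Xist 1220 CPM), 54.6 CPM in library 10 (Xist 153 CPM) and 132 CPM in library 11 (Xist 112 CPM), where 3 counts are worth at most 0.252 CPM. Library 11 also held the Y-linked Kdm5d (43.6 CPM) and Uty (37.0 CPM). Its Eif2s3y, Y-linked as well, was 0.058 CPM, less than 3 counts are worth there (0.173 CPM). Of the other libraries, Xist above 50 CPM without Ddx3y above 10 CPM was found in 4 sufficient and 3 deficient libraries, and Ddx3y without Xist in 3 sufficient and 8 deficient libraries. The remaining 2 libraries, of the sufficient group, were above neither limit. Library 6 still held both at low levels (Xist 5.64 CPM, Ddx3y 8.01 CPM), and library 2 had Xist at 1.12 CPM and Ddx3y at 0 CPM. Low Eif2s3y was not particular to library 11. Sufficient library 4 had Ddx3y at 39.8 CPM and Eif2s3y at 0.283 CPM, near what 3 counts are worth there (0.268 CPM). Bcl6 also stood apart in libraries 4 and 11, and a link was not tested. Without the 3 libraries that hold both, 1470 genes were called.

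The large number of genes that differ between groups was set against chance, depth and sex. Of 100 splits of the libraries drawn within runs, the real one included, 1 called as many as 2448 genes, and the highest of the others called 0. This argues against chance, as far as 100 splits can tell. With each library thinned to the smallest total, 2290 genes were called, and with Xist and Y-linked levels as covariates 2033, which argues against the deeper deficient libraries and the mix of sexes as the whole cause. The absence of T cells, the difference that the design names, remains open with other differences between the mice, such as litter or age at tumour, which were not tested.

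For the lower interferon gamma and MHC class II lists, RNA of macrophages left in the purified sufficient samples was weighed, since Lyz2, the most abundant gene of the macrophage list, averaged 153 against 38.5 CPM, and Cd68 79.3 against 41.5 CPM (adjusted p = 0.0508 in edgeR). None of the 20 genes of the macrophage list is in another list, and 19 of them have counts in these B cell samples. With the mean of that list as a covariate, the interferon gamma list's mean log2 difference was -0.71 ± 0.19 (SE) against -0.81 ± 0.21 without it, and that of MHC class II -0.99 ± 0.14 against -1.03 ± 0.14. Macrophage RNA as the whole cause is argued against for both lists, and part of the smaller change in the interferon gamma list may come from it. A lower exposure to interferon gamma where T cells are absent is a hypothesis that these data do not test.

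Run 2 called 1359 genes and run 1 called 0. Without T cell sufficient library 5, run 1 called 191, and scored by the genes called in run 2 this library lay at 0.49 on the log2 scale, within the run 1 deficient libraries (0.39 to 1.41) and apart from the other sufficient ones (-1.61 to -0.50). This library is a candidate cause of part of the gap, and whether its lymphoma resembles the other group or its label is wrong stays open. Depth is argued against, since the median total of run 1 was 1.25 times that of run 2. The labels of the run 2 deficient libraries carry sample numbers from a separate, higher range than those of all other libraries. What these numbers stand for is not given in the sources used here. Within run 2 the group difference cannot be told apart from whatever they mark, and its part in the gap was not tested. A wider spread between run 1 libraries cannot be told apart from an equal one: the ratio of biological coefficients of variation was 1.06, from 1.01 to 1.14 with 1 library left out. The 1.01 came from leaving out T cell sufficient library 5, so this ratio does not separate spread from that library.

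In the other counts of splits, as many genes as the 1359 in run 2 came from 1 of 100 splits (highest other 250), and as many as the 3999 between runs from 1 of 100 (highest other 1). Both argue against chance, as far as 100 splits can tell. For the 0 genes in run 1 and the 0 genes with an interaction, 100 of 100 splits gave as many, with up to 17 and 540 in the others, which a count of 0 always allows. The split with 540 interactions left 1 of the 11 libraries of run 2 and 6 of the 12 of run 1 in their real group, so it nearly mirrored the real groups in run 2 and mixed them in run 1. As many as 14 lists past the camera test came from 6 of 100 splits (highest other 16), so chance cannot be excluded for the number of lists.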

How the results depend on the processing

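The alternatives with covariates, thinned counts, the 3 libraries left out and within-run settings, and the permutation of list means, were chosen after the data were examined. The number of genes that differ stayed within 1.5 times of 2448 under 14 of 19 alternatives, and with each library left out in turn it ran from 1945 to 2783. It was 0 in run 1 alone (12 libraries) and 1359 in run 2 alone (11 libraries). Library number does not account for the gap between the runs, since run 1 held more. The count was 253 in a test against a 1.5-fold change, 1027 at an adjusted p of 0.01 and 1470 without the 3 libraries that hold Xist and Y-linked transcripts. Tnfsf9 was higher in each of its 16 alternatives (log2 fold change 1.42 to 2.67, adjusted p 4.52e-06 to 0.253) and past the threshold in all but run 1 alone (1.42), and 1.88 to 2.47 with each library left out. The labels of the groups share replicate numbers, but of 11 pairs only 4 had deviations that correlated above 0.1 (from -0.25 to 0.23) and 1 number correlated best with itself, so the numbers do not pair the samples; with the replicate number as a block, 1832 genes were called, Tnfsf9 had a log2 fold change of 2.56 and 15 lists passed. The number of lists was 0 with an estimated correlation, 12 to 15 under the other 12 alternatives and 13 to 17 with each library left out. Within-run counts with each library left out were 0 to 191 in run 1 and 528 to 1716 in run 2, and limma-voom called 0 and 1179. The count of genes with an interaction was 0 under both of its alternatives and that between runs 3995 and 4016. The smaller distance between deficient animals was -0.15 to -0.046 with each library left out, -0.23 by Euclidean distance (no longer past the threshold) and 0.0032, reversed, over pairs of the same run; the cause was not tested. Bcl6, which passed no test, changed sign with Xist and Y-linked covariates (-0.018) and without sufficient library 8 (-0.0029) or 12 (-0.010), with a range up to 0.43 over the libraries left out. Alternatives with the repeat library, and those without immunoglobulin genes, were not run because no such columns or genes were used here. With every library thinned to the smallest total, 2290 genes were called, so depth moved this count little, and of simulated 1.5-fold changes 49.3% were recovered over both runs. Counting limits the lowest genes, since 3 counts are worth 0.0980 to 0.396 CPM.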

Other observations

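The tests in this part were all fixed before the data were examined. The TNF superfamily, to which Tnfsf9 belongs, moved both ways in T cell deficient lymphomas: 3 of 20 measured members rose, 3 fell and 14 did not pass (3 rose and 4 fell when adjusted over the list alone). Beside Tnfsf9, Cd70, the ligand of CD27 on T cells, rose 4.47-fold, from 15.1 CPM ± 25.9 (SD, n = 12) to 51.2 CPM ± 13.6 (SD, n = 11; edgeR adjusted p = 0.00722). Tnfsf14, the ligand LIGHT, rose 5.54-fold (log2 fold change 2.47 ± 0.63 SE, adjusted p = 0.00888). Tnfsf9, Cd70 and Tnfsf14 lie near one another on chromosome 17, between 57105325 and 57194177. Whether they changed together as a region was not tested. Ltb, which encodes lymphotoxin beta, was 2.99-fold lower (log2 fold change -1.58 ± 0.40 SE, adjusted p = 0.00788). The list as a whole did not pass camera (adjusted p = 0.869), while fry's test for changes in either direction did (adjusted p = 1.13e-08). Regulators of apoptosis likewise moved apart, with 4 of 23 higher, 1 lower and 18 not passing (4 and 1 when adjusted over the list alone; camera adjusted p = 0.672). Bcl2, a survival factor that germinal centre B cells hold low, was 3.16-fold lower and below every sufficient library in 10 of 11 deficient ones (adjusted p = 0.008). Bcl2l1, a related survival factor, was 3.29-fold higher, as were the pro-apoptotic Bmf (3.28-fold) and Bid (1.53-fold).

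Among genes mutated in lymphoma, 6 of 32 rose, 6 fell and 20 did not pass (6 and 8 when adjusted over the list alone; camera adjusted p = 0.869). Ezh2, a histone methyltransferase, rose 1.79-fold (adjusted p = 0.00104) and Ccnd3, a cyclin, 2.76-fold (adjusted p = 0.00107). Of 19 plasma cell genes, 5 fell and 14 did not pass (5 when adjusted over the list alone; camera adjusted p = 0.125, 0.0362 in run 1 and 0.412 in run 2). Ly6c2 was 25.7-fold lower and Pdia4, a chaperone of the secretory pathway, 3.60-fold lower. In the TGF-beta list, 1 of 11 members rose and 2 fell, Tgfbr2 (2.01-fold lower, adjusted p = 0.00023) and Smad3 (5.31-fold lower), with a camera adjusted p of 0.0905 (0.0487 in run 1, 0.309 in run 2) and a fry adjusted p of 0.00118. With an estimated correlation over both runs, the TGF-beta list had a camera adjusted p of 0.218. In the list of early B cell precursors, 4 of 12 rose, among them Kit, a growth factor receptor (7.61-fold, from 0.835 CPM), and Flt3 (2.76-fold), with a camera adjusted p of 0.0628 (0.35 in run 1, 0.00621 in run 2) and a fry adjusted p of 0.0146. The precursor list's camera adjusted p with an estimated correlation over both runs was 0.356. Of 18 immediate early genes, 4 rose, Dusp1, Dusp2, Egr1 and Egr3, by 2.00-fold to 2.71-fold (camera adjusted p = 0.244). In the NF-kB and CD40 list, 1 of 23 rose and 1 fell (adjusted p = 0.642).

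Of 29 type I interferon genes, 0 passed the test in edgeR (2 at an unadjusted p under 0.05), and the list's median was 0.14 in run 1 and -0.69 in run 2, where it passed camera (adjusted p = 7.17e-05). Over both runs its camera adjusted p was 0.207, and 0.866 with an estimated correlation. Of 27 oxidative phosphorylation genes 0 passed in edgeR (4 unadjusted, camera adjusted p = 0.869), and of 11 heat shock genes 0 (1 unadjusted, camera adjusted p = 0.672). Of 22 glycolysis and hypoxia genes, 2 fell (adjusted p = 0.862), and of 5 ligands of NK cell receptors, 1 fell (adjusted p = 0.835). The median of these last 2 lists was positive (0.042 and 0.14) where the mean (-0.035 and -0.0064) and the test pointed lower.

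Markers of other cells gave mixed values. Of 12 T cell genes, 1 rose and 1 fell (camera adjusted p = 0.716). Zap70, a kinase of T cells that some B cell tumours also express, was 174 CPM ± 219 (SD, n = 11) in deficient and 16.3 CPM ± 36.3 (SD, n = 12) in sufficient lymphomas (log2 fold change 3.59 ± 1.23 SE, adjusted p = 0.04). Of 9 erythroid genes, 1 rose and 8 did not pass (camera adjusted p = 0.164). In run 1 this list passed as higher (adjusted p = 0.00062, median 1.24), while in run 2 its median was -0.65 (adjusted p = 0.911). With an estimated correlation over both runs, the erythroid list had a camera adjusted p of 0.813. Of 6 NK cell genes, 1 rose (adjusted p = 0.676), and of 7 dendritic cell genes, 2 rose, Xcr1 and Flt3, and 1 fell, Ccr9 (adjusted p = 0.672). In the monocyte and macrophage list, Ccr2 and Lyz2 fell and 17 of 19 did not pass. That list and the list of early B cell precursors each passed camera in 8 of 23 fits with 1 library left out. Adjusted over the list alone, the counts of the lists from the TGF-beta list onward were the same except in glycolysis and hypoxia (1 lower), T cell (1 higher, 2 lower) and dendritic cell genes (2 higher, 3 lower). The neutrophil list (4 tested genes) and the megakaryocyte list (1 tested gene) were too short to test.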
